A study of Mus musculus with 4 samples.

How the data were processed

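Poly(A) RNA was sequenced from the skull vault (calvaria) of mouse embryos at embryonic day 14.5. Per the labels, 2 libraries came from the frontal bone and 2 from the parietal and interparietal bones, which share each of these libraries. The labels give no strain, sex, litter or number of embryos per library, and do not say whether the libraries of a group came from separate animals.

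The values used were the deposited counts, 1 whole number per gene and library, not normalized. Per the submitters' processing notes the authors used Trim Galore 0.6.7, HISAT2 2.1.0, featureCounts 2.0.1 and the mouse genome build GRCm38. The order and settings of these steps, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Where the counting split reads between near-identical copies (alpha and beta globin genes, the Bglap cluster), or between a gene and its antisense or overlapping neighbour, the value of a gene is uncertain. Among genes with a deposited count of 1 to 20, even counts made up 74.4% and 68.3% of values in frontal libraries 1 and 2 and 73.0% and 71.3% in parietal-interparietal libraries 1 and 2, where chance gives about 50%. Even counts in such excess are what counting both mates of a read pair would give, so the counts were also analysed halved. No per-sample column was left unmapped.

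The file held 55487 Ensembl gene IDs, of which 33641 had a count above 0 in some library. Symbols, positions and gene types came from the GENCODE annotation of GRCm38, in which 55141 IDs had a match and 346 had none. Positions printed are 1-based GRCm38 coordinates of whole genes. Total counts were 29598388 and 35555013 in the frontal libraries and 24069177 and 26645504 in the parietal-interparietal libraries. A count of 3 corresponded to 0.104, 0.0852, 0.123 and 0.111 CPM in these 4 libraries. CPM stands for counts scaled to a common library size, in edgeR's standard unit, with library sizes corrected by the trimmed mean of M-values (TMM). Intervals on shares of counts are 95% Wilson intervals, and they and the floor of 3 counts cover counting error only.

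The comparison was frontal minus parietal-interparietal. Genes were filtered with filterByExpr (minimum count 10), which left 20947 genes. Counts were scaled by TMM and tested two-sided with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with group as the only term and 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called. Every adjusted p of a gene below comes from this edgeR test unless another tool is named. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Where all libraries of a group were at 0, the fold was computed against a floor of 3 counts over the group and written as a lower bound.

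Before the data were examined, 32 gene lists with 694 entries (643 distinct genes) were fixed, covering bone, mineralization, citrate and vesicle genes, patterning factors, other cell types, pathways and RNA quality. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its p-values from the 2 residual degrees of freedom of the fit, so it has little power here. Of the list entries, 21 did not pass the filter. The rule for named genes, fixed at the same time, had 3 parts. It took the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 CPM and both frontal libraries on one side of both parietal-interparietal libraries, leaving out numbered gene models. It always took Slc13a5, Slc25a1, Ank, Runx2, Sp7, Alpl, Phospho1, Spp1, Ibsp, Bglap, Dmp1 and Col1a1, and up to 4 members of each list with the smallest unadjusted p. This gave 144 genes, and the text names a part of them. Values of some genes are not reported here. Acly, Slc39a1, Nefm and Nefl lie outside the rule, were chosen after their values were seen and were not followed singly through the alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

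The procedure was tested on simulated data with the means and library sizes of these 4 libraries, 200 changed genes and 20227 genes past the filter. For this comparison it recovered 28.4% of genes simulated with an absolute log2 fold change of 0.5, 70.1% of those with 1 and 87.9% of those with 2. It called 8 unchanged genes, none of the calls on changed genes had the wrong sign, and camera called the 1 changed list and 0 of 30 unchanged lists. The simulated genes varied independently of each other, and each had the same dispersion in both groups. The simulation therefore does not show how camera at the preset correlation behaves where genes of a list vary together.

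Alternatives fixed before the data were examined were a replicate block, leaving out each library in turn, relative log expression size factors, no scaling beyond the total count, no filter, a stricter filter (at least 50 counts), removal of haemoglobin and mitochondrial genes, DESeq2 1.42.0, limma-voom, robust quasi-likelihood and camera with an estimated correlation. Chosen after seeing the data were protein-coding genes only and without Lars2, counts halved, the 2 parietal-interparietal libraries summed as 1 sample, an offset for GC content and length (spline with 5 degrees of freedom), and 5 further gene lists used only in the closing observations. No splits of the samples were counted, because each group had 2 libraries.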

Results

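The series belongs to a study of extracellular vesicles that carry citrate and of their use in promoting biomineralization. Its transcriptome part asks how the frontal bone of the embryonic skull vault differs from the parietal and interparietal bones in the mid-gestation mouse embryo, when ossification of the vault begins. The frontal bone arises mainly from cranial neural crest and the parietal bone mainly from head mesoderm. Because the interparietal bone shares the parietal libraries, the groups cannot be read as a plain contrast of these origins. There were 2 libraries per group. Nothing in the labels says that they came from separate embryos, so p-values measure only the spread between these samples, which may be technical.

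Between 24069177 and 35555013 counts were assigned to genes per library. Reads at an annotated locus that matches ribosomal RNA (CT010467.1) made up 9.86% of counts in frontal library 1 (95% Wilson interval 9.85 to 9.87) and 8.03% in frontal library 2 (8.02 to 8.04), against 6.07% (6.06 to 6.08) and 5.97% (5.96 to 5.97) in parietal-interparietal libraries 1 and 2. Mitochondrial ribosomal RNA made up 0.939% (0.935 to 0.942) and 1.12% (1.11 to 1.12) of counts in frontal libraries 1 and 2, and 0.564% and 0.567% in parietal-interparietal libraries 1 and 2.

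The libraries of a group were compared with each other before they were averaged. Between the 2 parietal-interparietal libraries the variance of the counts was 2.88 times that of binomial sampling for genes with 20 to 100 counts, 3.24 times for genes with 2000 to 10000 counts and 6.53 times (95% bootstrap interval 4.57 to 9.21) for genes with more. Between the 2 frontal libraries it was 5.20, 21.7 and 254 times. The parietal-interparietal libraries differed by more than sampling noise and were entered as 2 samples, as the labels list them. Such a difference could also be found between 2 libraries made from 1 RNA, so counts of calls with the pair summed as 1 sample are given beside the main counts.

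**Figure D1:**
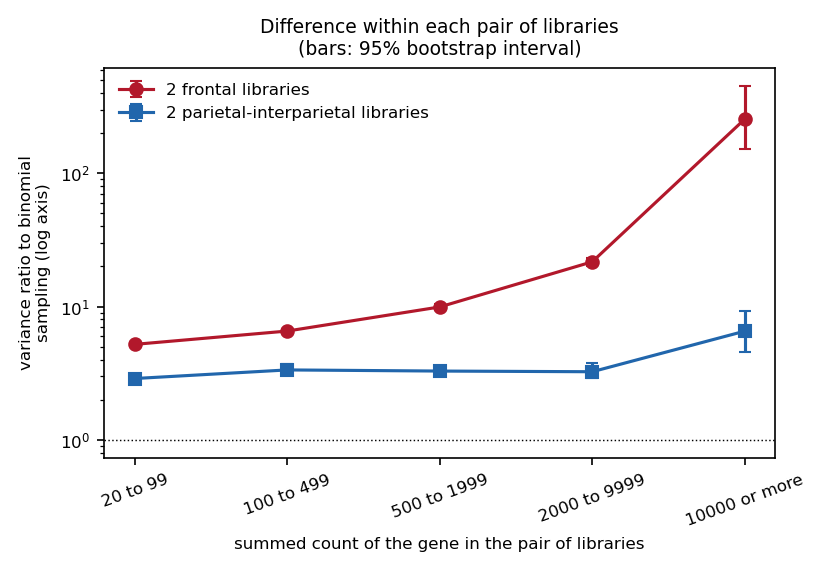
Variance of the difference between the libraries of a group, as a ratio to binomial sampling (log axis), against the summed count of a gene in the pair of libraries. Bars are 95% bootstrap intervals over genes. From the lowest to the highest bin the frontal pair went from 5.20 to 254 and the parietal-interparietal pair from 2.88 to 6.53.

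Transcription factors of the developing cerebral cortex were among the genes with the largest excess in the frontal libraries. Eomes, a T-box factor of cortical intermediate progenitors (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), was at 53.5 ± 0.220 CPM in frontal and 0.160 ± 0.121 CPM in parietal-interparietal libraries (mean ± SD, n = 2 each; log2 fold change 8.39 ± 0.24 SE, edgeR adjusted p = 3.2e-08). Emx1, a homeobox factor of the dorsal telencephalon (ENSMUSG00000033726, chromosome 6, 85187438 to 85204462), was at 20.1 ± 1.69 against 0.0818 ± 0.116 CPM (log2 fold change 7.94 ± 0.41, adjusted p = 2.63e-06). Tbr1 and Neurod6, factors of cortical excitatory neurons, had log2 fold changes of 7.83 ± 0.27 and 6.06 ± 0.18. Pth, which encodes parathyroid hormone, Rhcg, an ammonium transporter, and Drc7, a part of the axoneme of motile cilia, had no count in the parietal-interparietal libraries and were at least 40.5-fold, 39.1-fold and 37.2-fold higher in frontal libraries. Cyp2g1, a cytochrome P450 of the olfactory mucosa, had a log2 fold change of 5.67 ± 0.65.

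At the other end, the 8 genes with the lowest log2 fold changes included En2 and Tal2. En2, an engrailed homeobox factor of the midbrain-hindbrain boundary (ENSMUSG00000039095, chromosome 5, 28165694 to 28172166), was at 0.835 ± 0.345 CPM in the frontal libraries (n = 2) and at 14.1 and 14.9 CPM in the 2 parietal-interparietal libraries (log2 fold change −4.09 ± 0.27, edgeR adjusted p = 1.35e-05). Tal2, a basic helix-loop-helix factor of midbrain GABAergic neurons, had a log2 fold change of −2.79 ± 0.28, and the AP-2 family factor Tfap2d one of −3.03 ± 0.52. Tecta and Tectb, which encode the tectorins of the inner ear's tectorial membrane, had log2 fold changes of −2.77 ± 0.18 and −4.41 ± 0.33, and Otol1, which encodes otolin, one of −2.74 ± 0.50. Ddn, which encodes dendrin, and the helix-loop-helix factor Bhlhe23 completed the 8 lowest, at −4.13 ± 0.53 and −2.92 ± 0.65. Bhlhe23 lost its call without parietal-interparietal library 1 and with that pair summed as 1 sample, and Otol1 lost its call without parietal-interparietal library 2. The other genes of these 16 kept their call in every alternative in which they were tested.

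**Figure D2:**
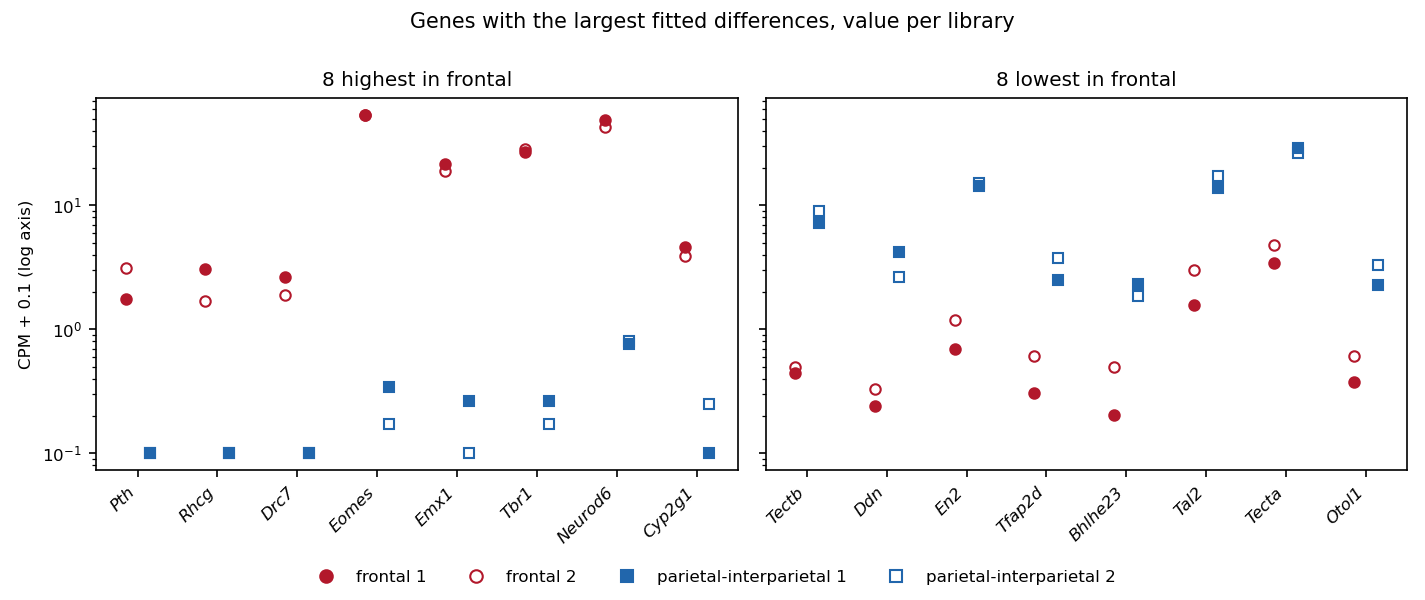
CPM plus 0.1 (log axis) in each of the 4 libraries for the 8 genes with the highest and the 8 with the lowest fitted log2 fold change under the fixed rule. Circles are frontal and squares parietal-interparietal libraries, filled for replicate 1 and open for replicate 2. Group means run from 53.5 against 0.160 CPM for Eomes to 0.373 against 8.06 CPM for Tectb, and the rule takes only genes whose groups do not overlap.

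Over all genes, 2657 of 20947 tested genes were called, 1309 higher and 1348 lower in frontal libraries, and 5668 had an unadjusted p under 0.05. Of the called genes 642 differed at least 2-fold, 371 higher and 271 lower. All libraries of the parietal-interparietal group were at 0 for 25 called genes, and both frontal libraries for 8. Counts within gene lists also changed with 1 library left out, and are given that way too. Their order is frontal library 1, frontal library 2, parietal-interparietal library 1 and parietal-interparietal library 2. Such a fit takes its residual spread from the pair left whole. The number of calls rose without either frontal library and fell without either parietal-interparietal library. It was 5373 without frontal library 1, 7279 without frontal library 2, 882 without parietal-interparietal library 1 and 865 without parietal-interparietal library 2. With the parietal-interparietal pair summed as 1 sample it was 791, of which 787 were also called with 4 samples, all in the same direction. The 2-fold count was 1712 without frontal library 2 and 417 with the pair summed. With no scaling beyond the total count 984 genes were called higher and 1606 lower, a share of 38.0% higher against 49.3% with TMM scaling.

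Bone genes went both ways. Of 25 tested osteoblast genes, 2 were higher, 3 lower and 20 not called (5 higher and 4 lower adjusted over the list alone). Ibsp, which encodes bone sialoprotein (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469), was 2.13-fold higher in frontal libraries, at 86.8 ± 7.89 against 40.8 ± 0.139 CPM (n = 2 each; log2 fold change 1.09 ± 0.10, edgeR adjusted p = 0.000118). The type I collagen chains were lower, Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) by 1.53-fold at 981 ± 19.5 against 1496 ± 9.02 CPM (log2 fold change −0.61 ± 0.06, adjusted p = 0.000315) and Col1a2 by 1.40-fold. Cthrc1, a secreted collagen triple helix repeat protein, had a log2 fold change of −0.96 ± 0.15. The libraries also held markers of other tissues, so the type I collagen difference cannot be assigned to bone cells. Of 28 collagen and matrix genes 14 were lower and 0 higher, and of 21 markers of the meninges 11 were lower and 1 higher.

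The regulators of the osteoblast lineage were not called. Runx2 was at 16.1 ± 0.371 CPM in frontal and 12.1 ± 1.97 CPM in parietal-interparietal libraries (adjusted p = 0.113), and Sp7 had a log2 fold change of −0.34 ± 0.15 (adjusted p = 0.171). The late osteoblast genes Bglap and Dmp1 were under 1 CPM in both groups. Bglap was at 0.764 ± 0.197 and 0.542 ± 0.506 CPM and Dmp1 at 0.444 ± 0.136 and 0.458 ± 0.185 CPM. Without frontal library 1, and also without frontal library 2, Runx2 was called higher. The osteoblast list as a whole was not called (camera adjusted p = 0.832), and its median of −0.05 and mean of 0.03 log2 units differed in sign. Osteoblast counts with 1 library left out were 6, 7, 1 and 1 higher and 6, 6, 3 and 3 lower.

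Of 20 tested genes of the mineralization machinery, 1 was higher (Ibsp), 1 lower and 18 not called (3 higher and 1 lower adjusted over the list alone). The lower gene was Pdpn, which encodes podoplanin, at −0.53 ± 0.09 log2 units, and it lost its call with the parietal-interparietal pair summed and without parietal-interparietal library 2. Alpl, which encodes tissue-nonspecific alkaline phosphatase, was at 21.8 ± 5.05 against 15.2 ± 0.300 CPM (adjusted p = 0.0635) and was called higher without frontal library 1 and with no filter. Ank, a membrane protein that exports pyrophosphate and citrate, was at 17.3 ± 2.27 and 18.6 ± 0.0615 CPM (adjusted p = 0.676). Spp1, which encodes osteopontin, was at 6.18 ± 0.821 and 5.21 ± 0.962 CPM (adjusted p = 0.543). Phospho1, a phosphatase of matrix vesicles, had 0 counts in all 4 libraries. The list was not called (camera adjusted p = 0.922), with a median of −0.07 and a mean of 0.05 log2 units. Mineralization counts with 1 library left out were 3, 2, 1 and 1 higher and 6, 4, 1 and 0 lower.

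The citrate transporters Slc13a5 and Slc25a1 were not called. Slc13a5, the plasma membrane citrate transporter (ENSMUSG00000020805, chromosome 11, 72241989 to 72267222), was at 3.74 ± 0.0695 CPM in frontal and 3.60 ± 0.227 CPM in parietal-interparietal libraries (n = 2 each; log2 fold change 0.06 ± 0.26, edgeR adjusted p = 0.922). Slc25a1, the mitochondrial citrate carrier (ENSMUSG00000003528, chromosome 16, 17925223 to 17928219), was at 44.4 ± 2.77 and 38.4 ± 1.49 CPM (0.21 ± 0.10, adjusted p = 0.212) and was called higher without frontal library 2. Of 28 tested genes of citrate handling and the tricarboxylic acid cycle, 1 was higher, 5 lower and 22 not called (3 higher and 6 lower adjusted over the list alone). Fumarase, encoded by Fh1, was 1.70-fold lower in frontal libraries (160 ± 20.6 against 272 ± 4.03 CPM, adjusted p = 0.000755). Citrate synthase (Cs) and the cytosolic isocitrate dehydrogenase Idh1 were 1.35-fold and 1.52-fold lower, as were the citrate-cleaving enzyme Acly and the zinc transporter Slc39a1 at −0.38 and −0.32 log2 units. The mitochondrial malate dehydrogenase Mdh2 was 1.30-fold higher. In the same libraries 17 of 22 muscle markers were lower and 0 higher, and 11 of 24 neural markers were higher and 5 lower. The differences of these citrate genes therefore cannot be assigned to bone cells. Calls of Cs and Mdh2 were lost without either parietal-interparietal library and with that pair summed, and in each of these settings 2 genes of the list were called lower, Fh1 and Idh1. The list was not called (camera adjusted p = 0.383), and its median of 0.02 turned to −0.03 with no scaling beyond the total count, while its mean was −0.08. Citrate list counts with 1 library left out were 7, 6, 0 and 0 higher and 8, 9, 2 and 2 lower.

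Of 28 tested genes of the machinery that forms extracellular vesicles, 3 were higher, 1 lower and 24 not called (3 higher and 2 lower adjusted over the list alone). The higher genes were Smpd2, a neutral sphingomyelinase (1.57-fold), the tetraspanin Cd82 (1.31-fold) and the ESCRT-III subunit Chmp4b (1.28-fold). The lower gene was Pdcd6ip, which encodes the ESCRT-associated protein ALIX (1.29-fold). Adjusted p-values of these 4 genes lay between 0.0165 and 0.0401. All 4 calls were lost with the parietal-interparietal pair summed and without parietal-interparietal library 2, those of Cd82, Chmp4b and Pdcd6ip also without library 1, and that of Cd82 also with no scaling beyond the total count and in DESeq2. The list was not called (camera adjusted p = 0.927), and its median of 0.00022 turned to −0.05 with no scaling beyond the total count. In the same libraries 11 of 24 neural markers were higher in frontal libraries and 17 of 22 muscle markers lower, as given with the other cell types. Vesicle list counts with 1 library left out were 7, 4, 1 and 0 higher and 7, 6, 0 and 0 lower.

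**Figure D3:**
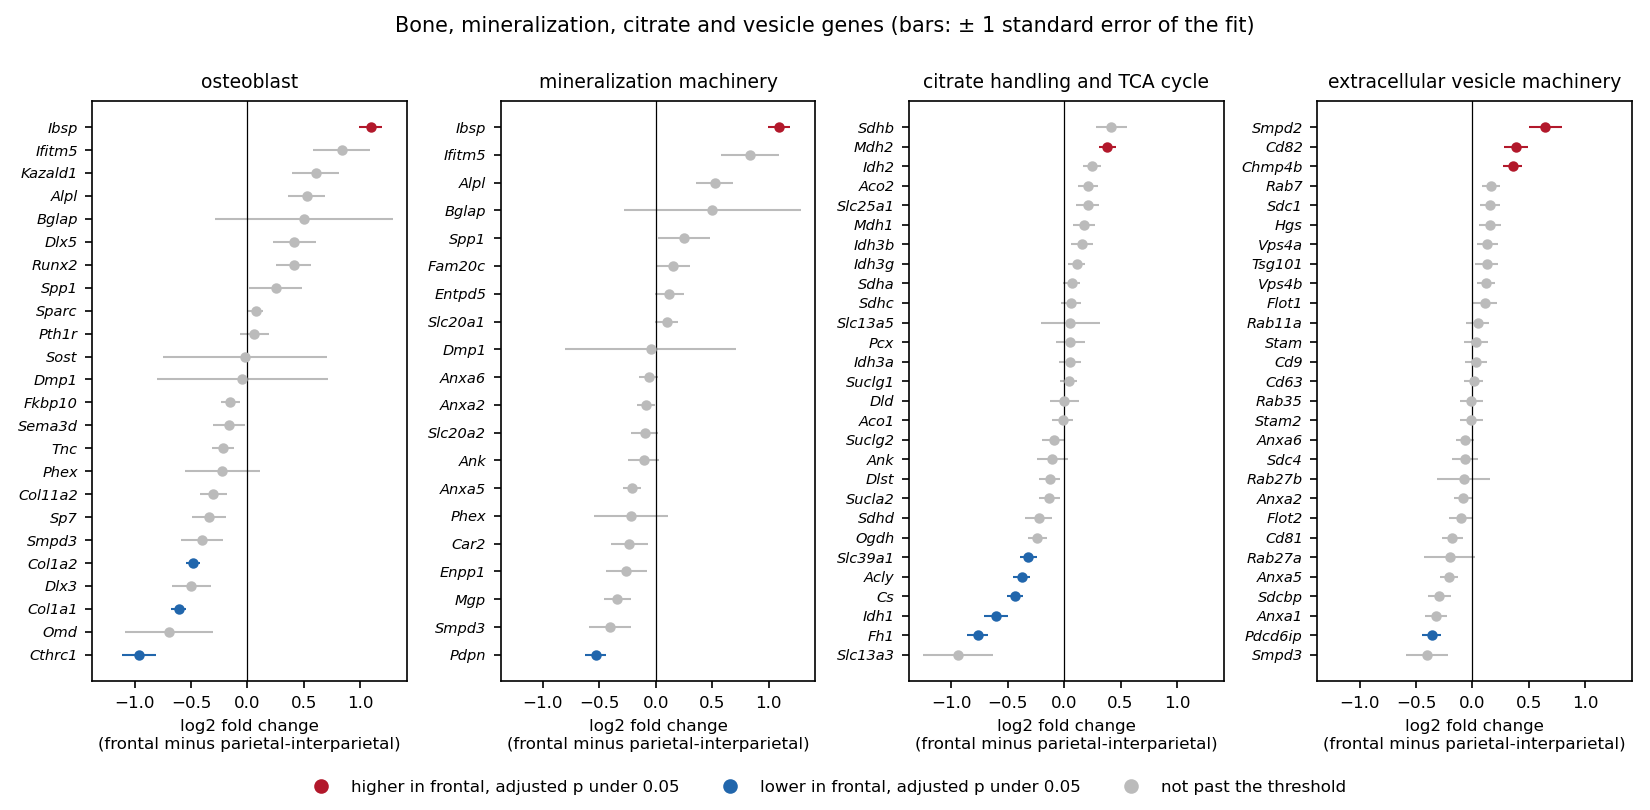
Log2 fold change (frontal minus parietal-interparietal, 2 libraries each) of the tested members of the osteoblast, mineralization, citrate and vesicle lists, with bars of 1 standard error. Red marks genes called higher and blue genes called lower in frontal libraries. In the 4 lists 2, 1, 1 and 3 genes were called higher, and 3, 1, 5 and 1 lower, and 1 osteoblast gene is not drawn.

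Genes of the HOX clusters of paralog groups 1 to 5, which mark the head and neck behind the anterior hindbrain, were lower in frontal libraries as a list (median −0.82 log2 units, camera adjusted p = 0.00176). With an estimated correlation the adjusted p = 0.259. Only Hoxb4 of the 14 tested members was called by itself, at 1.68 ± 0.357 against 4.48 ± 0.962 CPM (n = 2 each, edgeR adjusted p = 0.019), and 5 members were lower adjusted over the list alone. That call was lost without parietal-interparietal library 1 and with the pair summed. Midbrain and anterior hindbrain genes were also lower in 15 of 23 members and sensory ganglion genes in 16 of 21, with 0 higher in each. Those lists were written after the largest differences had been seen. HOX counts with 1 library left out were 0 higher each time and 2, 8, 0 and 1 lower.

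Of 26 transcription factors of the neural crest and frontonasal region, 6 were higher, 8 lower and 12 not called (7 higher and 11 lower adjusted over the list alone). Nr2f1, a nuclear receptor, and Msx1, a homeobox factor of skull and tooth mesenchyme, were 1.67-fold and 1.66-fold higher in frontal libraries. Six2 and Pax7, homeobox factors of craniofacial mesenchyme and of muscle progenitors, were 1.92-fold and 2.06-fold lower. The list was not called (camera adjusted p = 0.586). Its median of −0.13 turned to 0.09 without frontal library 1. Neural crest counts with 1 library left out were 8, 7, 4 and 3 higher and 10, 11, 4 and 3 lower.

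Of 18 transcription factors of paraxial and cranial mesoderm, 2 were higher, 3 lower and 13 not called (2 higher and 6 lower adjusted over the list alone). The higher genes were Lhx2, a LIM homeobox factor that is also abundant in forebrain, 6.95-fold at 105 ± 12.6 against 15.1 ± 0.653 CPM (adjusted p = 5.29e-07), and Pitx1, a homeobox factor of the first arch and of oral ectoderm, 5.11-fold. The list was not called (camera adjusted p = 0.807). Its camera direction was higher in frontal, while its median of −0.25 and mean of −0.15 were lower. Mesoderm counts with 1 library left out were 2, 3, 2 and 2 higher and 6, 6, 0 and 0 lower.

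Of 25 genes of the sutures and osteoprogenitor mesenchyme, 3 were higher, 7 lower and 15 not called (3 higher and 8 lower adjusted over the list alone). Fgfr3, a fibroblast growth factor receptor of cartilage that neural progenitors also express, was 3.79-fold higher in frontal libraries (93.9 ± 1.76 against 24.8 ± 1.20 CPM, adjusted p = 1.82e-06). En1, also among the midbrain and anterior hindbrain genes of the closing observations, was 2.48-fold lower. Six2 was 1.92-fold lower and Dlk1 1.37-fold lower, the last losing its call without either parietal-interparietal library and with the pair summed. The list was not called (camera adjusted p = 0.169). Suture counts with 1 library left out were 5, 3, 2 and 2 higher and 11, 14, 3 and 2 lower.

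Markers of other tissues of the head differed between the groups. Of 24 neuron and neural progenitor genes, 11 were higher, 5 lower and 8 not called (11 higher and 5 lower adjusted over the list alone; camera adjusted p = 3.97e-19, and adjusted p = 0.166 with an estimated correlation). The higher members were led by the forebrain factors Neurod2 (34.5-fold, 49.0 ± 0.275 against 1.42 ± 0.133 CPM), Neurod6 (66.6-fold) and Pax6 (6.12-fold). The lower members included the neurofilament genes Nefm and Nefl at −1.17 and −1.28 log2 units. Neural counts with 1 library left out were 12, 14, 9 and 9 higher and 5, 8, 4 and 4 lower.

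Markers of the meninges, the membranes around the brain, were lower in frontal libraries. Of 21 tested members 1 was higher, 11 lower and 9 not called (1 higher and 16 lower adjusted over the list alone; median −0.57, camera adjusted p = 4.86e-14, adjusted p = 0.166 with an estimated correlation). Ptgds, which encodes prostaglandin D synthase, was 2.77-fold lower (71.8 ± 9.96 against 199 ± 1.91 CPM), the tight junction gene Cldn11 2.31-fold, the transporter gene Slc6a13 2.25-fold and the connexin gene Gjb2 1.89-fold. Meningeal counts with 1 library left out were 1, 1, 0 and 0 higher and 15, 16, 7 and 9 lower.

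Skeletal muscle genes were lower in frontal libraries in 17 of 22 tested members, with 0 higher (18 lower adjusted over the list alone; median −0.54, camera adjusted p = 2.28e-12, adjusted p = 0.166 with an estimated correlation). Embryonic myosin Myh3 was 1.47-fold lower at 374 ± 8.75 against 551 ± 6.27 CPM, cardiac actin Actc1 1.46-fold and fast troponin Tnni2 1.60-fold. Erythroid genes were lower in 8 of 15 members, with 0 higher (11 adjusted over the list alone; median −0.76, camera adjusted p = 2.96e-07, adjusted p = 0.184 with an estimated correlation). They included the anion exchanger gene Slc4a1 (2.20-fold) and the embryonic globins Hba-x and Hbb-bh1 (1.87-fold and 1.76-fold), whose reads may be shared with other globin genes. Muscle counts with 1 library left out were 0 higher each time and 21, 19, 5 and 7 lower. Erythroid counts with 1 library left out were 0 higher each time and 11, 11, 4 and 5 lower.

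Collagen and matrix genes were lower in 14 of 28 members, with 0 higher (16 adjusted over the list alone; median −0.29, camera adjusted p = 1.97e-06, adjusted p = 0.184 with an estimated correlation). Besides the type I chains they included Col5a1, 1.48-fold lower, and the proteoglycan Bgn, 1.38-fold lower, the latter losing its call without either parietal-interparietal library and with the pair summed. With that pair summed 3 matrix genes, 7 muscle genes and 1 macrophage or leukocyte gene were called lower. Of 18 dermal fibroblast genes 1 was higher and 5 lower (1 and 8 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.259 with an estimated correlation), with Pdgfra 1.73-fold lower. Of 20 macrophage and leukocyte genes 6 were lower, with 0 higher (9 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.259 with an estimated correlation), led by Laptm5 at 1.69-fold, a call lost without parietal-interparietal library 2. Matrix counts with 1 library left out were 2, 1, 0 and 0 higher and 19, 19, 3 and 4 lower. Dermal counts with 1 library left out were 2, 2, 0 and 0 higher and 10, 8, 2 and 2 lower. Macrophage and leukocyte counts with 1 library left out were 0, 2, 0 and 0 higher and 10, 11, 1 and 0 lower.

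Lists of 4 further cell types were also called lower in frontal libraries. The adipocyte list held 12 genes, of which Adipoq, Plin1, Cidec, Retn and Lep did not pass the filter and were not tested. Of 14 Schwann cell and melanocyte genes 4 were lower (5 adjusted over the list alone; camera adjusted p = 0.00867, adjusted p = 0.354 with an estimated correlation). Of 7 adipocyte genes 2 were lower (3 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.354 with an estimated correlation, and 0.102 without frontal library 1), with the carbonic anhydrase gene Car3 1.71-fold lower and the fatty acid receptor gene Cd36 1.90-fold. Of 20 epidermal genes 3 were lower, Cdh1, Krt10 and Grhl3 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.354 with an estimated correlation). Of 20 endothelial and pericyte genes 1 was higher and 2 were lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.0328, adjusted p = 0.354 with an estimated correlation), with the cadherin gene Cdh5 1.54-fold lower and the claudin gene Cldn5 1.33-fold higher. The calls of Cldn5, Cd36, Krt10 and Grhl3 were lost without either parietal-interparietal library and with the pair summed, and that of Cdh1 without parietal-interparietal library 1 and with the pair summed. The epidermal and endothelial lists lost their calls without frontal library 2 (camera adjusted p = 0.18 and 0.156) and without parietal-interparietal library 1 (0.0808 and 0.0556). Schwann cell counts with 1 library left out were 1, 0, 0 and 0 higher and 6, 6, 1 and 1 lower. Adipocyte counts with 1 library left out were 0 higher each time and 2, 5, 1 and 1 lower. Epidermal counts with 1 library left out were 1, 3, 0 and 0 higher and 8, 9, 0 and 1 lower. Endothelial counts with 1 library left out were 2, 2, 0 and 0 higher and 9, 7, 1 and 1 lower.

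The cartilage and osteoclast lists were not called (camera adjusted p = 0.402 for each). Among 21 chondrocyte genes 2 were higher and 4 lower, also adjusted over the list alone. The factors Sox5 and Sox6, which neurons also express, were 2.39-fold and 1.71-fold higher, while the cartilage collagen gene Col2a1 was 1.35-fold lower, a call lost without either parietal-interparietal library and with the pair summed. Among 9 osteoclast genes 2 were lower, also adjusted over the list alone, namely Ctsk and Nfatc1. Both calls were lost without either parietal-interparietal library and with the pair summed. Chondrocyte counts with 1 library left out were 2, 2, 2 and 2 higher and 6, 5, 1 and 1 lower. Osteoclast counts with 1 library left out were 0, 3, 0 and 0 higher and 5, 3, 0 and 0 lower.

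**Figure D4:**
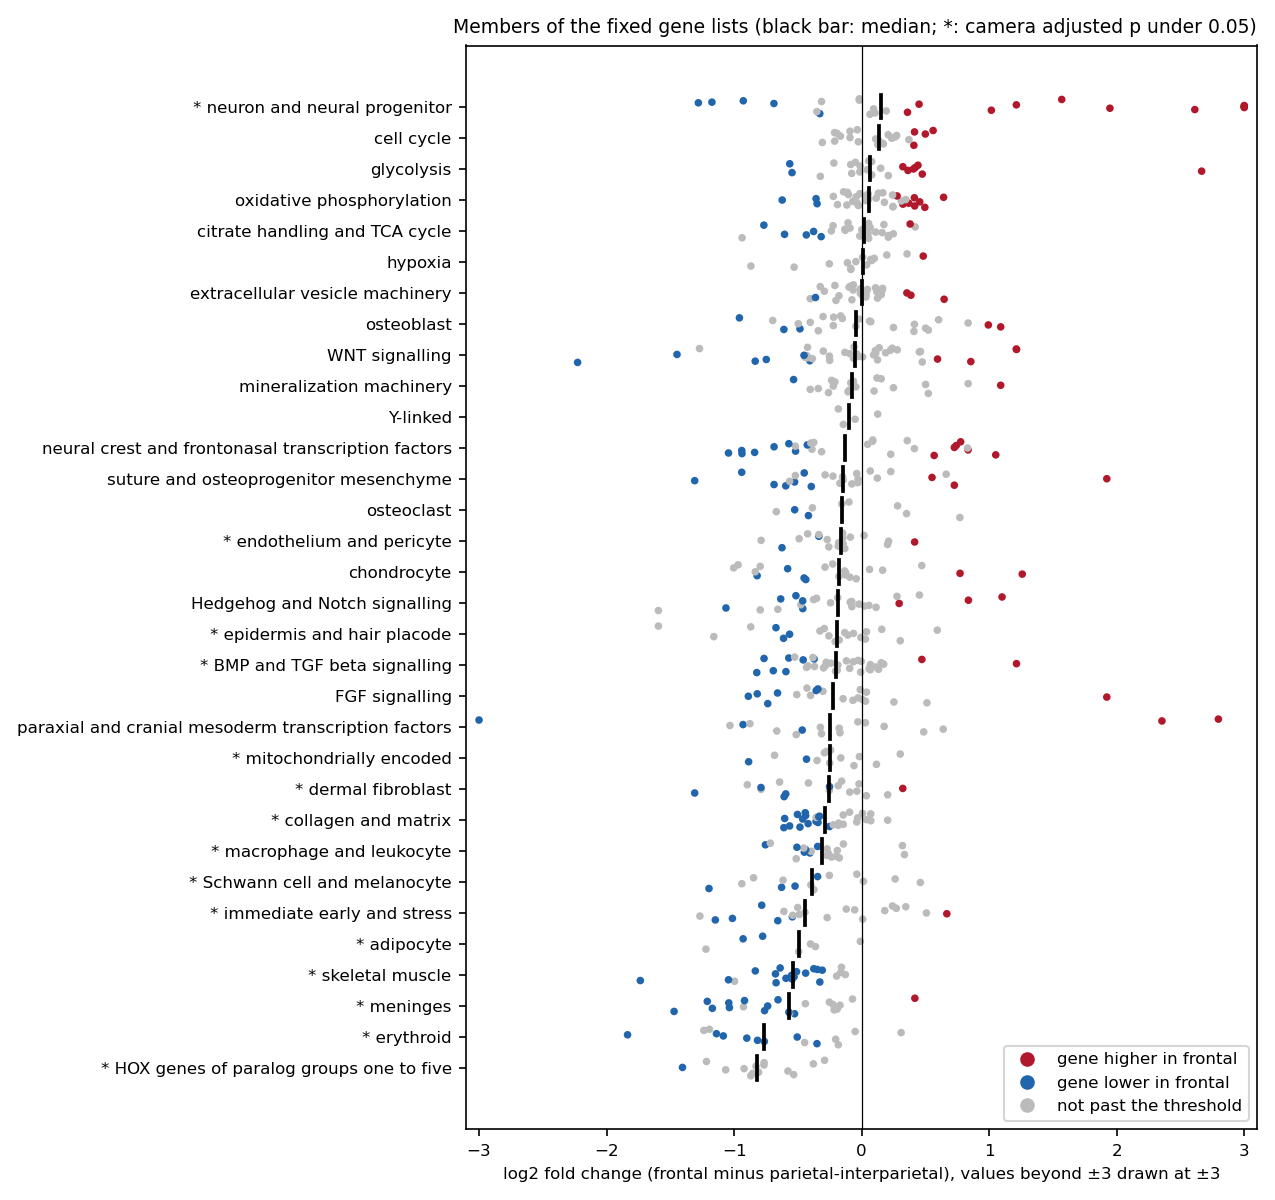
Log2 fold changes (frontal minus parietal-interparietal) of the tested members of all 32 lists, with the median as a black bar and values beyond 3 log2 units drawn at the edge. Asterisks mark the 15 lists called by camera at the preset correlation, of which 1 (neuron and neural progenitor) was higher and 14 were lower in frontal libraries.

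Markers of neural and other tissues differed between the groups, so differences of the signalling genes below cannot be assigned to bone cells. Of 38 WNT genes 4 were higher and 6 lower (the same numbers adjusted over the list alone), with the R-spondin genes Rspo2 and Rspo3 each 2.32-fold higher and Wnt6 1.68-fold lower. Of 34 BMP and TGF beta genes 2 were higher and 7 lower (2 and 9 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.595 with an estimated correlation), with Id4 2.32-fold higher and Tgfbr3 1.70-fold lower. That list lost its call without frontal library 1 (0.142) and without parietal-interparietal library 2 (0.0617). Of 20 FGF genes 1 was higher and 6 lower (1 and 10 adjusted over the list alone). Fgfr3 was the higher gene, and Fgfr4 and the feedback inhibitor Spry2 were 1.85-fold and 1.76-fold lower, Spry2 losing its call without parietal-interparietal library 2. Of 25 Hedgehog and Notch genes 3 were higher and 5 lower (4 and 7 adjusted over the list alone), with Hey1 2.15-fold and the Notch ligand gene Dll1 1.79-fold higher, and the ligand gene Jag1 1.55-fold lower. Jag1 lost its call without parietal-interparietal library 2. The WNT, FGF and Hedgehog and Notch lists were not called (camera adjusted p = 0.756, 0.169 and 0.169), the last being called lower without frontal library 1 (0.0365). WNT counts with 1 library left out were 7, 8, 2 and 2 higher and 10, 13, 1 and 2 lower. BMP and TGF beta counts with 1 library left out were 5, 3, 1 and 1 higher and 11, 14, 2 and 2 lower. FGF counts with 1 library left out were 1, 1, 1 and 1 higher and 8, 10, 2 and 1 lower. Hedgehog and Notch counts with 1 library left out were 3, 6, 2 and 2 higher and 8, 9, 1 and 1 lower.

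Of 23 cell cycle genes 4 were higher and 0 lower (5 higher adjusted over the list alone), with Cenpf 1.47-fold, Mcm7 1.41-fold, and Mki67 and Tyms each 1.33-fold higher. All 4 calls were lost with the parietal-interparietal pair summed and without parietal-interparietal library 2, those of Mcm7, Mki67 and Tyms also without library 1, and the list was not called (camera adjusted p = 0.0787), but was called higher without frontal library 1 (0.0021). Of 22 glycolysis genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0611, and 1.39e-05 without frontal library 2). Aldoc, an aldolase of the brain, was 6.35-fold higher, and the glucose transporter gene Slc2a3 1.48-fold lower, the latter losing its call without parietal-interparietal library 1 and with the pair summed. Of 35 nuclear genes of oxidative phosphorylation 8 were higher and 3 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.18, and 0.00105 without frontal library 1). With no scaling beyond the total count 4 were higher and 3 lower. Cell cycle counts with 1 library left out were 9, 9, 1 and 0 higher and 0, 7, 0 and 0 lower. Glycolysis counts with 1 library left out were 7, 11, 1 and 1 higher and 4, 5, 0 and 1 lower. Oxidative phosphorylation counts with 1 library left out were 17, 15, 0 and 0 higher and 8, 14, 1 and 1 lower.

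Among the lists kept for RNA quality, immediate early and stress genes had 1 member higher and 5 lower of 21 (2 and 5 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.354 with an estimated correlation), with Fosb 2.21-fold and Junb 2.02-fold lower in frontal libraries. That list lost its call without frontal library 2 (0.316). Of 13 mitochondrially encoded genes 2 were lower (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0492, adjusted p = 0.708 with an estimated correlation). The list lost its call without frontal library 1 (0.125), where its median of −0.25 turned to 0.09. Of the list, mt-Nd4 was 1.85-fold lower and mt-Nd5 1.35-fold, the latter losing its call without either parietal-interparietal library and with the pair summed. Mitochondrial ribosomal RNA (mt-Rnr2) was higher in frontal libraries, at 0.99 log2 units. Of 15 hypoxia genes 1 was higher, also adjusted over the list alone (Ddit4, 1.40-fold, with its call lost in the same 3 settings), and the list was not called (camera adjusted p = 0.835). Its median of 0.0078 turned to −0.04 with no scaling beyond the total count. Of the 4 Y-linked genes 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05. All 4 were expressed in both groups, with Ddx3y at 30.2 ± 2.77 and 33.4 ± 3.15 CPM. Immediate early counts with 1 library left out were 2, 6, 0 and 0 higher and 8, 7, 4 and 4 lower. Mitochondrially encoded counts with 1 library left out were 4, 1, 0 and 0 higher and 4, 11, 2 and 1 lower. Hypoxia counts with 1 library left out were 3, 2, 0 and 0 higher and 0, 1, 0 and 0 lower.

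In all, camera called 15 of the 32 lists. With an estimated correlation it called 0, with 5 at an unadjusted p under 0.05, and fry called 7 of the 15 (adjusted p under 0.05). The 0 calls say little, because at 2 residual degrees of freedom an adjusted p under 0.05 over 32 lists is hard to reach. Under the stricter filter the endothelial, epidermal, BMP and TGF beta and mitochondrially encoded lists lost their calls (camera adjusted p = 0.0547, 0.0856, 0.0552 and 0.0811). The mitochondrially encoded list also lost its call with protein-coding genes only (0.0719) and with counts halved (0.0558). With no filter the suture, FGF, cell cycle and glycolysis lists were called (0.0316, 0.0161, 0.0198 and 0.0427), and the last 2 also with the offset for GC content and length (0.0441 and 0.0432).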

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

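The alternatives with 3 samples rest on 1 residual degree of freedom and assume that the lone library varies like the other group. The pair left whole sets that spread. For genes with 2000 to 10000 counts the variance ratio to binomial sampling was 21.7 in the frontal and 3.24 in the parietal-interparietal pair. The count of called genes ran from 865 to 7279 when 1 library was left out, and the 2-fold count from 439 to 1712. With the parietal-interparietal pair summed, an alternative chosen after seeing the data, they were 791 and 417. In the other alternatives the counts lay within 1.5 times those with 4 samples. The replicate numbers did not pair the samples: over 12257 genes the difference between replicates 1 and 2 in frontal correlated with that in parietal-interparietal libraries at r = 0.0093 (across genes, which are not independent replicates). With the replicate number as a block 3306 genes, 768 at least 2-fold, and 15 lists (2 higher, 13 lower) were called, with the epidermal list losing its call (0.0503) and glycolysis gaining one (0.023). Alpl was also called higher under the block, where 3 genes of the mineralization list were. Camera with an estimated correlation, which rests on 2 residual degrees of freedom, called 0 of 32 lists, 5 of them with an unadjusted p under 0.05. Calls shared between settings kept their sign in each setting run. Of the 116 called genes among those the rule named, 62 kept their call in every alternative, 52 lost it only where a parietal-interparietal library was left out or the pair summed, 2 lost it in another alternative, and 0 reversed sign. The cause of these changes was not tested.

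Results that reversed were not called by the test with 4 samples. Adjusted p of the mineralization list was 0.859 with no filter and 0.988 with the stricter filter, and 0.885 to 0.994 with 1 library left out. The vesicle list had 0.856 with no scaling beyond the total count, 0.988 with the stricter filter and 0.885 to 0.994 with 1 library left out. The paraxial mesoderm list had 0.442 with no filter. With 1 library left out, log2 fold changes ran from −0.24 to 2.02 for Bglap, −0.41 to 0.44 for Dmp1, −0.0085 to 0.12 for Slc13a5, −0.24 to 0.014 for Ank, −0.061 to 0.29 for Kdm5d, −0.19 to 0.070 for Eif2s3y and −0.52 to 0.078 for Uty. Bglap and Dmp1 were under 1 CPM in both groups.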

Other observations

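Of 5 further lists, all written after the largest differences had been seen, 1 held genes of the choroid plexus and of motile cilia. Of its 20 genes 15 were higher in frontal libraries and 0 lower, with a median log2 fold change of 1.94, also with genes at 0 set at their bound (camera adjusted p = 0.0116 with an estimated correlation, adjusted over the 5 lists). Ttr, which encodes transthyretin, a major secreted protein of the choroid plexus, was at 748 and 778 CPM in the 2 frontal and 29.6 and 25.7 CPM in the 2 parietal-interparietal libraries. Kcne2, a potassium channel subunit, had a log2 fold change of 5.43, and Foxj1, a regulator of motile cilia, one of 2.46.

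Genes of sensory ganglia went the other way. Of 21 genes 16 were lower in frontal libraries and 0 higher, with a median of −1.17 (camera adjusted p = 0.0116 with an estimated correlation). The nociceptor sodium channel gene Scn10a had a log2 fold change of −2.04 and the homeobox gene Isl1 one of −1.67. Because these lists were chosen on the same libraries, their p-values are not independent evidence.

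Genes of the telencephalon were higher in frontal libraries in 17 of 21 members (median 3.26, camera adjusted p = 0.0116 with an estimated correlation), and genes of the midbrain and anterior hindbrain lower in 15 of 23 (median −1.31, 0.0326). Of these lists 10 and 3 genes are also in fixed lists. Of the called telencephalon genes 100% kept their call with protein-coding genes only, but that setting moved their log2 fold changes by a median of only 0.0051, so it leaves open what ribosomal RNA and non-coding reads did. Brain RNA in the dissected pieces may account for the pattern. A list of 21 genes expressed across the brain, not looked at before the test was set, had a median of at least 25.1 CPM in each library. Under 1 CPM was to count against brain RNA. That outcome was hardly possible, because brain genes had already been seen in both groups. Eomes was at 53.5 CPM in frontal and En2 at 14.1 and 14.9 CPM in parietal-interparietal libraries. The test therefore does not decide the question. A difference between the 2 regions in expression within the bones stays open and was not tested.

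The muscle, meninges, erythroid and matrix lists were called lower in frontal libraries at the preset correlation, with 17 of 22, 11 of 21, 8 of 15 and 14 of 28 genes lower, but not with an estimated correlation (adjusted p = 0.166, 0.166, 0.184 and 0.184), and with the pair summed 7, 7, 4 and 3 genes were lower. The estimated correlations of the muscle, meninges, erythroid and matrix lists were −0.044, −0.013, −0.051 and −0.030, all below the preset 0.01. Their lost calls are therefore no sign that genes of these lists vary together. Under equal dilution of all other tissues the lists of those tissues would fall alike. The mean log2 fold changes of 8 other-tissue lists, from −0.69 (erythroid) to 0.03 (osteoblast), moved apart (permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation moved genes between lists, so its p measures spread among genes and not between libraries. Genes of a list that vary together between libraries could also give such a p, so equal dilution is not excluded. More brain RNA in the frontal libraries may be part of the lower muscle, meninges, erythroid and matrix values. The brain-wide list had a median log2 fold change of 0.413 (95% bootstrap interval 0.0341 to 0.532). With an estimated correlation its camera adjusted p = 0.0427, adjusted over the further lists alone, and its unadjusted p was also 0.0427. The muscle, meninges, erythroid and matrix values above were adjusted over all fixed lists. Their unadjusted camera p-values with an estimated correlation were smaller, at 0.015, 0.0131, 0.0277 and 0.0288. The adjusted values of the fixed and further lists therefore cannot be compared directly. Of the genes of the brain-wide list 8 were higher and 3 lower. With frontal library 1, frontal library 2, parietal-interparietal library 1 or 2 left out 10, 11, 4 and 3 were higher and 3, 5, 0 and 1 lower, and its median CPM per library hardly separated the groups, at 25.1 and 29.6 in frontal and 28.6 and 28.2 in parietal-interparietal libraries. How much muscle, meninges and blood went with each piece, or a difference between the regions, stays open.

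The variance between the 2 parietal-interparietal libraries grew less with the count than that between the 2 frontal libraries, and both tests of this were chosen after the result was seen. A library deposited or sequenced again is argued against by a ratio to binomial sampling of 2.88 at 20 to 100 counts, above the 2 that counting both mates allows. Whether 1 RNA or pool was made into 2 libraries cannot be told apart from 2 similar samples. The ratio at 2000 to 10000 counts was 1.12 times that of the lowest bin, but that of genes with more counts was 2.27 times it (4.16 and 48.9 times for the frontal pair). No biological explanation was tested.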
